A study of Homo sapiens with 13 samples.

How the data were processed

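K562 cells, an established chronic myeloid leukaemia line, were labelled with 30 µM 4-thiouridine (4sU) for 12 h with the medium exchanged every 3 h, washed and chased with 3 mM uridine, per the labels' protocols. RNA was alkylated with iodoacetamide, mixed with Drosophila S2 RNA as a 5% spike-in and made into QuantSeq 3' mRNA libraries (SLAM-seq), per the labels' protocols. The 13 libraries were grouped by their titles into 6 chase times with 2 replicates each and 1 library without 4sU. The labels do not say that replicates are separate cultures, so p-values measure the spread between these samples, which may be technical.

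The authors deposited 3 tables of raw counts, namely counts of all reads per human gene, counts of the reads they call nascent per human gene, and counts per Drosophila gene. The submitters' processing notes name bcl2fastq 2.17.1.14, Trim Galore 0.6.5, bedtools and the builds hg38 and dm6. The aligner, the counter, the gene annotation, the use of strand and the number of conversions that makes a read nascent are not given in the sources used here. Reads that fit several genes may have been split or moved between near-identical copies, so globins, IFITM genes, histones, HSPA1B and pseudogenes are uncertain. Every column of the tables was matched to a library by its name. Of 59204 human gene IDs, 40541 were named from a table of gene names, 1022 from GENCODE 29, 14275 were known without a symbol and 3366 were not matched. Coordinates are the gene spans of GENCODE 29 on GRCh38 (hg38), counted from 1. Library depth is given as the total count, with a floor of 3 counts for a gene at 0 and 95% Wilson intervals for shares of single libraries.

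Decay was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, two-sided, Benjamini-Hochberg adjusted, false discovery rate 0.05). The slope of labelled counts on chase time was fitted over the 12 chase libraries with the log of the TMM effective size of the total library as offset, and its difference from the median slope was tested. Genes needed a mean of 5 CPM (counts scaled to library size) and 100 labelled counts in all. A quadratic term was tested in the same way. Apparent half-lives came from a quasi-Poisson fit per gene of an exponential plus the gene's labelled share without 4sU as background (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Their 95% intervals use the scaled standard error, and where the upper bound was over 48 h only the lower limit was read. Figures were drawn with matplotlib 3.10.9.

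Total counts were tested with edgeR over the 6 times and the library without 4sU as 7 groups that share 1 spread, with filterByExpr and TMM. The library without 4sU has no replicate and was assumed to vary like the others. Labelled share and the ratio of total to spike-in counts were computed per library, and the ratio was set against time with permutation tests.

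Before the data were examined, 24 gene lists, the designs, most alternatives and the rule for named genes were fixed. The lists were immediate early genes, haematopoietic transcription factors, ZNF genes, mitochondrially encoded mRNAs, p53 targets, ATF4 targets, ribosomal proteins, respiratory chain subunits, glycolysis, erythroid genes, proteasome subunits and BCL2 family genes. They were further elongation and BET genes, replication-dependent histones (named histones below), G1/S and G2/M genes, heat shock genes and cholesterol biosynthesis. The rest were small nucleolar RNA hosts, mRNA decay, interferon response, and markers of megakaryocytes, of granulocytes and monocytes and of lymphocytes. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated from the data.

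Named in the decay comparison were the 10 most and 10 least negative slopes among genes that passed and lay on the same side in both replicate series, the 2 shortest and 2 longest half-lives of each list, and 14 genes set in advance (MYC, MYB, MCL1, GATA1, ABL1, JUNB, IER2, BCL2L1, GAPDH, ACTB, EEF1A1, HBG1, HBG2 and TFRC). For total RNA these were the 5 largest rises and 5 largest falls per contrast among genes that passed, with groups that do not overlap and a mean of at least 5 CPM. Further members of lists were chosen after their values were seen, and some genes are not reported here.

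Alternatives were DESeq2 1.42.0 (size factors and test), spike-in totals as library sizes, each gene's own total as the offset, other filters (none, 500 labelled counts, genes over 2% labelled without 4sU left out), shorter time windows, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a window of 2 to 12 h, leaving out pseudogenes, and the spike-in composition side as a factor. The side was taken from the first principal component of spike-in genes with a mean of at least 200 counts.

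The count tests were tried on simulated data drawn from the real means and library sizes, with a fixed spread. Over 9652 genes the decay test found 94 of 100 genes with a slope changed by 0.15 and 31 of 100 changed by 0.05, with 3 false calls, and the quadratic test found 88 of 100 at 0.04 and 63 of 100 at 0.02, with 6 false. Over 16255 genes the test of 12 h found 79 of 100 genes changed by a log2 of 1 and 52 of 100 changed by 0.585, with 7 false. That of 1 h found 77 and 48, with 6 false, and that against no 4sU 75 and 38, with 3 false. Half-lives set to 1, 2, 4, 8 and 16 h were recovered as medians of 1.00, 2.01, 3.97, 8.05 and 15.9 h. Those genes had simulated starting levels, the real library sizes, 1 rate each and no background. Genes that depart from 1 rate were therefore not covered.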

Results

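The loss of metabolically labelled RNA was followed in K562 cells, an established human chronic myeloid leukaemia line that carries the BCR-ABL1 fusion and makes fetal globins. The cells were given 4-thiouridine (4sU), a uridine analogue that is built into new RNA, for 12 h, and were then washed and kept in medium with an excess of uridine. Libraries were made 0, 1, 2, 4, 8 and 12 h after the wash, with 2 replicates at each of the 6 times, and 1 further library came from cells that received no 4sU. RNA was alkylated so that 4sU is read as C, mixed with RNA of Drosophila S2 cells as a spike-in and sequenced from its 3' ends. For each gene the tables gave the count of all reads and the count of the reads that the authors call nascent, named labelled counts here.

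Total counts were 10064385 and 9004529 in the libraries of 0 h, 14501366 and 13769489 at 1 h, and 14315013 and 13522741 at 2 h. They were 12798505 and 11180308 at 4 h, 11951128 and 11739545 at 8 h, 11507151 and 12820690 at 12 h, and 17425584 without 4sU. A gene with a count of 0 could hold up to 1.72e-05% of the counts in the deepest library and up to 3.33e-05% in the shallowest. Between 19277 and 22624 genes had counts in a library, and the 10 most abundant genes took 8.01 to 12.1% of them. Intervals and floors cover counting error only, since no molecular identifiers were stated.

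The composition of the spike-in RNA, which came from another organism and did not go through the chase, separated the libraries. The first component of 648 abundant spike-in genes held 66.2% of their variance and placed 7 chase libraries (both of 0, 1 and 2 h and replicate 1 of 4 h) on one side. The other side held 5 chase libraries (replicate 2 of 4 h and both of 8 and 12 h), and the library without 4sU projected there as well, with a score of 2.24 against −3.13 and 2.69 for the replicates of 4 h. This split, which runs almost with chase time, was seen in the data, and values with the side as a factor stand beside the counts of each time and of the gene lists that passed. In the tests of total RNA only 4 h holds both sides, so the side was estimated from the difference between its 2 libraries alone. The values at 8 and 12 h and against no 4sU are shifted by that difference, and those at 4 h rest on replicate 1. At 1 and 2 h all libraries lie on the same side as those of 0 h, so the side adjusts nothing there except the estimated spread.

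The labelled share of all counts was followed to measure the loss of label. It was 36.0% ± 0.175 (SD, n = 2) at 0 h, 34.7% ± 0.315 at 1 h, 32.9% ± 0.264 at 2 h, 26.3% ± 0.0488 at 4 h, 16.8% ± 0.183 at 8 h and 10.75% ± 0.274 at 12 h. MYC, a transcription factor that drives growth, went from 78.5% ± 0.157 labelled at 0 h to 0.839% at 12 h. HBG1, a fetal globin with a near-identical copy (HBG2), was 37.1% ± 0.764 labelled at 0 h and 37.5% ± 0.622 at 12 h. Without 4sU, 0.00633% of counts were labelled (95% Wilson interval 0.00597 to 0.00671%). A straight line through the logarithm of the background-corrected share gave a half-life of 6.63 h ± 0.117 (SD, n = 2 replicate series), and 8.64 h over the first 4 h.

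**Figure D1:**
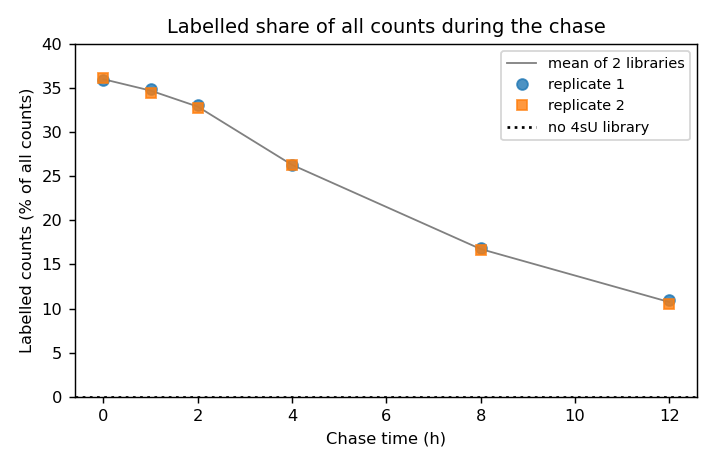
Labelled share of all counts in percent (vertical axis) against chase time in hours (horizontal axis), 1 point per library, with the library without 4sU shown apart. The mean of 2 libraries was 36.0% at 0 h and 10.75% at 12 h, and the share without 4sU was 0.00633%.

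Labelled RNA of MYC, MCL1 and GATA1 fell faster than that of the median gene, and that of GAPDH and EEF1A1 fell slower. Labelled RNA of MYC had an apparent half-life of 1.37 h (95% interval 1.11 to 1.78; 12 libraries) and that of MCL1, which protects cells from apoptosis, 2.59 h (2.11 to 3.34). GATA1, the central transcription factor of erythroid cells, had 2.91 h (2.30 to 3.96). Its labelled share was 44.6% ± 2.41 at 0 h, 43.4% ± 1.27 at 2 h, 29.6% ± 0.219 at 4 h and 1.37% ± 0.200 at 12 h (SD, n = 2). The share thus hardly fell over the first 2 h, and the single half-life of GATA1 describes neither part of the chase alone. GAPDH, a glycolytic enzyme, had 22.0 h (16.4 to 33.2) and EEF1A1, a translation elongation factor, 12.95 h (10.7 to 16.3). The labelled share of EEF1A1 was 23.8% at 0 h and 22.8% at 12 h, so that with its own total as the offset it had no finite half-life. ABL1, part of which belongs to the fusion of this line, had 4.44 h (3.42 to 6.31), but 2.49 h with its own total, where the median of all genes was 4.30 and 3.79 h.

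The question, named in the series title, was how fast each transcript decays, and the test asked which genes lost labelled RNA faster or slower than the median gene. Of 9652 genes tested, 3474 fell faster than the median slope of −0.24 log2 units per hour and 3506 fell slower, while 2672 passed in neither direction (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Of the 6980 genes that passed, 6972 lay on the same side of the median in both replicate series fitted alone. With each gene's own total as the offset, 2762 of the faster genes stayed faster, 585 passed in neither direction and 127 fell slower. Of the slower genes 3002 stayed slower, 393 passed in neither direction and 111 fell faster. The median half-life was 4.30 h (SD 0.0366, n = 2 series). The 10th and 90th percentiles were 2.30 and 10.9 h, 457 genes lay under 2 h, 787 lay over 12 h, and 317 gave only a lower limit. Medians were 4.22 h for 8429 coding genes, 3.76 h for 147 lincRNAs, 3.29 h for 128 antisense RNAs and 8.81 h for 738 annotated pseudogenes. Half-lives are apparent, since dilution by growth was not measured, and their median was 3.76 h over 2 to 12 h against 6.26 h over 0 to 4 h. With the spike-in side as a factor, 2093 genes fell faster and 2407 slower. Since the side runs almost with chase time, slopes are less precise in this fit. Calls can be lost there whether or not the side affected labelled counts.

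Immediate early genes, which respond to stimuli within minutes, fell faster in 23 of 24 tested members and slower in 0, with a median half-life of 1.88 h and an adjusted camera p of 8.8e-08. Adjusted over the list alone the count was 24, and the call was lost at adjusted p = 0.196 with an estimated correlation. In 10 of the 24, among them IER2, DUSP1, EGR1, KLF6, FOS and FOSB, labelled RNA was higher at 1 h than at 0 h, so that it did not fall from the start. Of the other 14 members 13 fell faster, with a median of 1.86 h, and over 2 to 12 h the median of the list was 1.79 h. JUNB (chromosome 19, 12791496 to 12793315, GRCh38) had 1.85 h (1.41 to 2.73) and IER2 (chromosome 19, 13150415 to 13154908) 2.32 h (1.79 to 3.27). PHLDA1 at 3.08 h did not pass (adjusted p = 0.0614) but fell faster with its own total. DUSP1, a phosphatase of MAP kinases (chromosome 5, 172768090 to 172771195), had 1.25 h (0.703 to 5.57) over the whole chase. Labelled counts at 0 and 1 h were 68 and 48 and then 218 and 175 for DUSP1, and 93 and 107 and then 147 and 170 for JUNB, which is no fall per library size in that hour. SGK1, a kinase, had 1.07 h (0.817 to 1.55). FOS had a slope of −1.10 ± 0.21 log2 units per hour (SE; adjusted p = 0.00293) on 7 counts at 0 h, and with its own total as the offset the slope lay 0.0375 above the median. With the spike-in side as a factor 18 of the 24 fell faster.

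Haematopoietic transcription factors fell faster in 17 of 21 members and slower in 2, adjusted over the list alone 17 and 2, with a median of 2.5 h (camera adjusted p = 8.5e-05, adjusted p = 0.198 with an estimated correlation; 14 faster with the side as a factor). NFE2, an erythroid bZIP factor (chromosome 12, 54292111 to 54301121), had 1.79 h (1.5 to 2.22), KLF1, an erythroid zinc finger factor (chromosome 19, 12884422 to 12887199), 1.90 h (1.55 to 2.45), and GATA1 (chromosome X, 48786554 to 48794311) an adjusted p of 3.6e-06. MYB, a factor of blood progenitors (chromosome 6, 135181315 to 135219173), had 3.81 h (3.33 to 4.46; adjusted p = 0.00799). STAT5A (chromosome 17, 42287547 to 42311943) and CBFB (chromosome 16, 67029116 to 67101058) had the longest half-lives, 6.04 and 6.69 h. With its own total as the offset the slope of STAT5A lay −0.0440 log2 units per hour from the median, and the half-lives of STAT5A and MYB were 3.34 and 2.3 h.

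Zinc finger genes with ZNF symbols fell faster in 198 of 241 members and slower in 8, adjusted over the list alone 203 and 8, with a median of 2.42 h (camera adjusted p = 9.2e-16, adjusted p = 0.196 with an estimated correlation; 139 faster with the side as a factor). ZNF526 (chromosome 19, 42220271 to 42228201) and ZNF134 (chromosome 19, 57614233 to 57624723) had 1.15 and 1.21 h, and ZNF428 and ZNF90 14.0 and 19.9 h, but 9.13 and over 48 h with their own totals. All 10 tested mitochondrially encoded mRNAs fell faster, adjusted over the list alone 10, with a median of 1.91 h (camera adjusted p = 3.5e-05, adjusted p = 0.196 with an estimated correlation; 9 with the side as a factor). MT-ND1 (chromosome M, 3307 to 4262) had 1.05 h (0.823 to 1.46; 1.89 h with its own total), MT-CYB (chromosome M, 14747 to 15887) 1.43 h, MT-ATP8 2.15 h and MT-ND4 2.27 h, all subunits of oxidative phosphorylation. Only 26.1% of MT-ND1 and 9.62% of MT-CYB counts were labelled at 0 h.

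Of 18 tested p53 targets 13 fell faster and 5 slower, adjusted over the list alone 13 and 5 (median 2.98 h; camera adjusted p = 0.0469, adjusted p = 0.412 with an estimated correlation; 9 faster with the side as a factor). The call was also lost without replicate 2 of 12 h (0.0543), with each gene's own total (0.0631) and over 0 to 4 h (0.131). PPM1D, a phosphatase that dampens p53, had 1.91 h and GADD45A, a stress sensor, 1.92 h, whereas BAX, which promotes apoptosis, had 7.03 h and RPS27L 11.9 h, or no finite value with its own total. Integrated stress response genes driven by ATF4 fell faster in 12 of 22 members and slower in 6, adjusted over the list alone 12 and 6 (median 2.84 h; camera adjusted p = 0.0298, adjusted p = 0.324 with an estimated correlation and 0.518 with each gene's own total; 12 with the side as a factor). CHAC1, which degrades glutathione (chromosome 15, 40952962 to 40956519), had 0.874 h (0.705 to 1.15) and went from 63.1% labelled to 0 labelled counts at 12 h. DDIT4, an inhibitor of mTORC1 (chromosome 10, 72273920 to 72276036), had 1.10 h (0.970 to 1.27), while the amino acid enzymes SHMT2 and ASNS had 10.1 and 10.8 h. With their own totals these 4 genes had 1.79, 1.73, 21.8 and 29.5 h.

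Cytosolic ribosomal protein genes fell slower in 81 of 83 members, adjusted over the list alone 81, with a median of 16.6 h, or 40.6 h with each gene's own total as the offset (camera adjusted p = 5.0e-33, adjusted p = 0.0421 with an estimated correlation; 80 with the side as a factor). RPS13 (chromosome 11, 17074389 to 17077787) had at least 41.4 h and RPL39 at least 28.0 h. RPL7L1 at 2.57 h was the 1 member that fell faster, and RPL22L1 at 4.34 h did not pass (adjusted p = 0.112). Nuclear encoded respiratory chain subunits fell slower in 73 of 76 members and faster in 2, adjusted over the list alone 73 and 2, with a median of 13.2 h, or 29.3 h with each gene's own total (camera adjusted p = 6.5e-25, adjusted p = 0.0421 with an estimated correlation; 72 slower with the side as a factor). UQCRH had 24.3 h (no finite value with its own total), ATP5MG at least 22.3 h, and UQCRFS1 and NDUFV3 3.39 and 3.61 h.

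Proteasome subunits fell slower in 32 of 35 members and faster in 2, with a median of 8.57 h (camera adjusted p = 5.9e-10, adjusted p = 0.196 with an estimated correlation; 28 slower with the side as a factor), from 3.61 h for PSMD7 to 19.4 h for PSMA7 (38.2 h with its own total). Glycolysis genes fell slower in 15 of 18 and faster in 2, with a median of 11.05 h, or 18.3 h with each gene's own total (camera adjusted p = 3.5e-05, adjusted p = 0.196 with an estimated correlation; 14 slower with the side as a factor). GPI, an isomerase (chromosome 19, 34359480 to 34402413), had 23.3 h and GAPDH (chromosome 12, 6533927 to 6538374) an adjusted p of 1.5e-17, while the glucose transporters SLC2A1 and SLC2A3 had 2.92 and 3.27 h. With their own totals GPI had over 48 h and SLC2A3 1.96 h. Erythroid and globin genes fell slower in 23 of 35 and faster in 5, with a median of 7.14 h (camera adjusted p = 1.8e-04, adjusted p = 0.196 with an estimated correlation; 18 slower with the side as a factor). HBG1 (chromosome 11, 5248079 to 5249859) had 20.4 h (15.6 to 29.6), HBG2 (chromosome 11, 5253190 to 5505605) 19.3 h and ALAS2, the erythroid haem synthesis enzyme, at least 11.7 h, against 2.55 h for the erythropoietin receptor EPOR. The labelled shares of HBG1 and HBG2 were the same within 1 SD at 0 and 12 h, so that with their own totals neither had a half-life under 48 h. Adjusted over the list alone these counts of slower members were 32, 15 and 23.

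TFRC, the transferrin receptor (chromosome 3, 196027183 to 196082189), had 4.27 h (3.8 to 4.88; adjusted p = 0.156) and ABL1 (chromosome 9, 130713946 to 130887675) an adjusted p of 0.462. With each gene's own total as the offset both fell faster, at 2.81 and 2.49 h. Between 0 and 12 h their totals rose from 167.6 to 498 CPM (TFRC) and from 51.7 to 168 CPM (ABL1). A rising total lowers the labelled share by itself, so these shorter values do not show faster decay. ACTB, cytoplasmic actin (chromosome 7, 5527147 to 5563784), fell slower with 9.42 h (8.08 to 11.3; adjusted p = 7.2e-15). MYC (chromosome 8, 127735434 to 127741434) had a slope of −0.66 ± 0.03 log2 units per hour (SE; adjusted p = 2.5e-12), MCL1 (chromosome 1, 150574551 to 150579738) an adjusted p of 2.5e-09, and BCL2L1, which like it protects from apoptosis (chromosome 20, 31664452 to 31723989), 2.31 h (1.91 to 2.90). The most negative slope, −1.51 ± 0.11, belonged to the lincRNA ENSG00000264066 (chromosome 17, 28861072 to 28861966), followed by CHAC1 at −1.14 ± 0.06. Of the 10 least negative slopes, 5 belonged to named pseudogenes, such as RPS3AP26, 89.3% labelled at 0 h and 93.7% at 12 h, and 1 to GTF2H4, a TFIIH subunit (chromosome 6, 30908184 to 30914106), at 0.05. The labelled share of GTF2H4 nevertheless fell from 45.9% at 0 h to 8.60% at 12 h, while its total rose from 12.4 to 71.6 CPM.

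The other 10 tested lists did not pass. Small nucleolar RNA host genes had 7 faster and 12 slower of 24 (camera adjusted p = 0.0556, adjusted p = 0.324 with an estimated correlation). At the preset correlation they passed with a replicate block (0.0495), the side as a factor (0.0215), each gene's own total (0.00227) and over 2 to 12 h (0.00744). They passed as well without replicate 1 of 0 h (0.035), of 1 h (0.0492) or of 8 h (0.0456) and without replicate 2 of 0 h (0.0385). BCL2 family genes had 6 and 2 of 11 (0.134), interferon response genes 1 and 6 of 8 (0.134) and cholesterol biosynthesis genes 12 and 7 of 23 (0.141). With each gene's own total 4 of the cholesterol genes fell faster and 12 slower. Heat shock and chaperone genes had 8 and 12 of 21 (0.443), from 1.53 h for DNAJB1 to 17.5 h for HSP90AB1, a chaperone of kinases (chromosome 6, 44246166 to 44253888; 8.83 h with its own total). Genes of mRNA decay had 24 and 21 of 60 (0.650), from 1.65 h for the CCR4-NOT ligase CNOT4 to 12.8 h for LSM7, and transcription elongation and BET genes 12 and 15 of 36 (0.788), from 1.79 h for CCNT2, a P-TEFb cyclin, to 19.0 h for POLR2E (over 48 h with its own total). G1/S genes had 10 and 11 of 27, G2/M genes 11 and 10 of 31 and histones 4 and 3 of 13 (each 0.876), with 2.62 h for KIF23 and 19.1 h for the securin PTTG1 (chromosome 5, 160421822 to 160428744), or 4.53 and 10.2 h with their own totals. The median slopes of the histones and the G2/M genes lay 0.019 and 0.000875 above that of all genes, against the sign of their tests. With each gene's own total 0 histones fell faster and 10 slower. Only 13 of 70 replication-dependent histone genes had enough counts to test. Adjusted over the list alone the counts were the same except 13 slower host genes and 13 faster elongation genes. Of marker lists of other blood cells, 0 of 12 megakaryocyte genes, 2 of 14 granulocyte and monocyte genes (CD33 at 4.55 h and LYZ at 12.1 h, without a finite value with its own total) and 1 of 14 lymphocyte genes (CD3D at 9.08 h) had enough labelled counts to test.

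**Figure D2:**
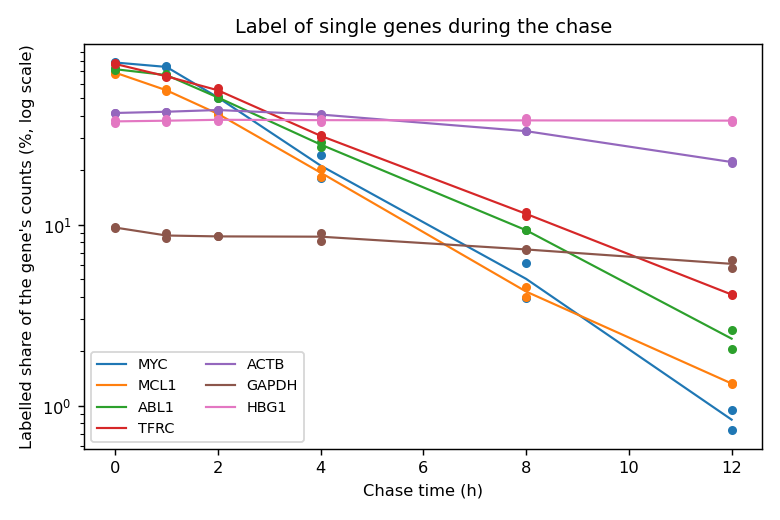
Labelled share of each gene's counts in percent (vertical axis, log scale) against chase time in hours (horizontal axis) for 7 genes, with 1 point per library and lines through the means of 2 replicates. From 0 to 12 h the mean share went from 78.5% to 0.839% for MYC, and from 37.1% to 37.5% for HBG1.

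**Figure D3:**
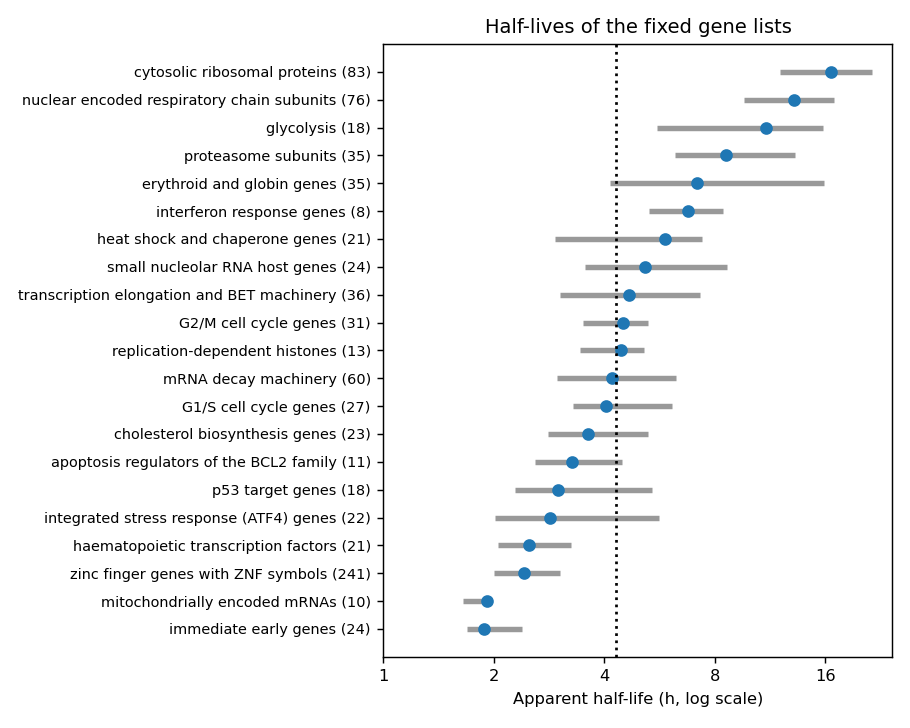
Apparent half-life in hours (horizontal axis, log scale) for each gene list tested (vertical axis, number of tested members in brackets), with the median as a dot and the quartiles as a bar. Medians run from 1.88 h for immediate early genes to 16.6 h for ribosomal proteins, and the dotted line is the median of all genes, 4.30 h.

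The next question was whether 1 rate described a gene over the whole chase. Labelled RNA of 3210 genes fell faster later in the chase than earlier, and that of 52 genes fell slower later (edgeR test of a quadratic term, adjusted, 9652 genes). MYB was among the former, with a quadratic term of −0.0131 in labelled counts per library size (adjusted p = 3.6e-04). Its labelled counts, before scaling, were 858 and 813 at 0 h, 921 and 953 at 2 h, 712 and 652 at 4 h and 100 and 105 at 12 h. Its labelled share was 69.9% ± 0.801 at 0 h, 51.5% ± 0.423 at 2 h, 20.3% ± 0.152 at 4 h and 2.63% ± 0.0748 at 12 h (SD, n = 2). This share does not show the tested term, since it also depends on total RNA of MYB, at 133 CPM at 2 h and 274.5 CPM at 4 h. For TFRC and HBG1 the term did not pass (adjusted p = 0.110 and 0.911). With the spike-in side as a factor the counts were 3396 and 51, and over 2 to 12 h 366 genes fell faster later.

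Total RNA was compared with 0 h at each time, which shows how steady the transcriptome was while label was lost. At 1 h a small set of immediate early genes was higher. FOS (chromosome 14, 75278774 to 75282230), an AP-1 subunit, was at 68.1 ± 18.6 CPM (counts scaled to library size; SD, n = 2) against 0.375 ± 0.208 at 0 h, a log2 fold change of 7.44 ± 0.32 (SE; edgeR adjusted p = 1.7e-15). FOSB (chromosome 19, 45467995 to 45475179), another AP-1 subunit, was at 54.8 ± 7.39 against 0.818 ± 0.0259 CPM (6.05 ± 0.27; edgeR adjusted p = 3.4e-15). EGR1 (chromosome 5, 138465490 to 138469315), a growth-responsive zinc finger factor, rose from 8.06 ± 1.2 to 99.95 ± 6.90 CPM (3.64 ± 0.14; edgeR adjusted p = 3.3e-16). At 12 h EGR1 was at 24.7 ± 1.75 and FOSB at 0.874 ± 0.315 CPM.

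At 1 h 52 of 16255 genes were higher and 6 lower (edgeR quasi-likelihood test; 87 and 17 with the side as a factor). Of 34 tested immediate early genes 15 rose and 0 fell (16 and 1 with the side as a factor), and adjusted over the list alone 23 rose and 2 fell. The list passed with camera adjusted p = 4.5e-49 and held with an estimated correlation (adjusted p = 6.3e-05). It was the 1 list that passed at 1 h, but without replicate 1 or 2 of 0 h 3 and 5 lists passed, and without replicate 1 or 2 of 1 h 3 and 2. Members picked after their values were seen were KLF6, a zinc finger factor (chromosome 10, 3775996 to 3785281), which rose from 62.0 ± 7.21 to 272.5 ± 13.6 CPM, JUN (1.61 ± 0.11; adjusted p = 1.7e-10), DUSP1 (2.13 ± 0.21; adjusted p = 2.5e-07) and JUNB (0.78 ± 0.11; adjusted p = 9.9e-05). OSR2, a zinc finger factor (chromosome 8, 98944403 to 98952104), rose by 3.53 ± 0.17 and MIR23AHG, a microRNA host (chromosome 19, 13823880 to 13842928), by 4.26 ± 0.16. Lower at 1 h were the lincRNA ENSG00000264066 (−2.94 ± 0.19; adjusted p = 1.9e-11), ENSG00000240975 (−1.30 ± 0.21), MCM3AP-AS1 (−0.74 ± 0.17), LINC00685 (−0.69 ± 0.14) and SNHG12 (−0.45 ± 0.07). Antisense and host genes among them are uncertain, since the use of strand in counting was not given in the sources used here. Leaving out 1 of the 4 libraries of 0 and 1 h in turn left 29 to 34 genes higher, leaving out either of 0 h left 3 lower, and leaving out either of 4 h gave 87 higher and 17 or 18 lower.

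At 2 h 853 genes were higher and 281 lower (1052 and 486 with the side as a factor; 912 and 73 with spike-in scaling). MYC had fallen from 94.1 ± 2.66 to 32.2 ± 0.372 CPM (−1.55 ± 0.13; adjusted p = 2.4e-09) and was at 53.6 CPM at 4 h. Without 1 library of 0 or 2 h the counts at 2 h were 403 to 556 higher and 89 to 126 lower, and without either of 4 h 487 or 488 were lower. CHAC1 had changed by −1.58 ± 0.20 (adjusted p = 4.0e-06), and FOSB (5.75 ± 0.27), FOS (3.65 ± 0.46), OSR2 (2.81) and LINC00324 (1.88 ± 0.29) were higher. At 4 h 2709 genes were higher and 2525 lower (2302 and 2102 with the side as a factor; 3119 and 1040 with spike-in scaling). BUD13, a splicing factor (2.24 ± 0.26), and TAF1, a TFIID subunit (chromosome X, 71366239 to 71532374; 1.99 ± 0.12), were among the largest rises, and FGF18, a growth factor, changed by −2.41 ± 0.18. Without 4sU BUD13 was at 10.6 CPM and TAF1 at 135, above their levels of 0 h. Without replicate 1 of 0 h, 1459 genes were lower at 4 h.

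By 12 h total RNA of HDAC7, TFRC and MYB had risen and that of FGF18, DDIT4 and INSIG1 had fallen. HDAC7, a histone deacetylase (chromosome 12, 47782722 to 47833132), rose from 39.3 ± 2.70 to 322 ± 24.9 CPM (SD, n = 2; log2 3.04 ± 0.09; edgeR adjusted p = 1.0e-19). TFRC, picked after its values were seen, rose by 1.57 ± 0.07 (edgeR adjusted p = 8.2e-17). FGF18 (chromosome 5, 171419656 to 171457623) went from 26.7 ± 0.949 to 0.927 ± 0.0699 CPM (−4.84 ± 0.23; edgeR adjusted p = 1.3e-15). In the library without 4sU HDAC7 was at 820.5, TFRC at 316, MYB at 255, FGF18 at 0.186, DDIT4 at 77.8 and INSIG1 at 123 CPM, so that the changes of these 6 genes ran toward or past their levels without the pulse.

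At 8 h 3857 genes were higher and 4128 lower (2514 and 2429 with the side as a factor; 5467 and 2008 with spike-in scaling). At 12 h the counts were 4388 and 4737 (2911 and 3118 with the side as a factor; 6570 and 2226 with spike-in scaling), and 10133 genes changed over the 6 times (6917 with the side as a factor). Spike-in scaling moved the median of all genes by 0.13 at 4 h, 0.29 at 8 h and 0.41 at 12 h (log2), so that smaller changes than these can turn with the scaling. Other large rises at 12 h were those of RAI14 (chromosome 5, 34656237 to 34832627; 3.18 ± 0.16; adjusted p = 2.1e-15), FAM216A (chromosome 12, 110468364 to 110490385; 3.18 ± 0.12), ADCK2 (3.02 ± 0.24) and ST6GAL1, a sialyltransferase (chromosome 3, 186930485 to 187078553; 2.99 ± 0.13). At 8 h EPOP (2.66), FAM216A (2.63), ST6GAL1 (2.62) and TRIB2, a pseudokinase (chromosome 2, 12716889 to 12742734; 2.60 ± 0.10), were highest beside the pseudogene RPL12P19 (2.74). Without 4sU the levels were 54.4 CPM for RAI14, 133 for FAM216A, 11.1 for ADCK2, 143 for ST6GAL1, 15.2 for EPOP and 108 for TRIB2, each above that of 0 h, but 0.557 for RPL12P19, below it. Pseudogenes led the falls, with RPS24P6 from 1383 to 22.6 CPM at 12 h (−5.94 ± 0.11; adjusted p = 2.0e-24) while its labelled share went from 4.66% to 40.7% (5.82 CPM without 4sU), PFN1P1 at −4.70, BTF3P5 at −6.24 and BTF3P7 at −6.09. With the side as a factor BTF3P5 and BTF3P7 did not pass at 12 h (−1.74 and −1.84). At 8 h FGF18 was at −4.91 and CHAC1 at −3.8 ± 0.25.

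Of the fixed lists, 8 passed at 12 h. Ribosomal protein genes had 1 higher and 76 lower of 84, adjusted over the list alone 1 and 78, but 10 higher and 12 lower with spike-in scaling (camera adjusted p = 5.6e-15, adjusted p = 0.484 with an estimated correlation; 1 and 72 with the side as a factor). Nuclear encoded respiratory chain genes had 7 and 62 of 76, with 13 and 15 under spike-in scaling (camera adjusted p = 7.4e-11, adjusted p = 0.491 with an estimated correlation; 4 and 57 with the side as a factor). Mitochondrially encoded mRNAs had 1 and 7 of 12 (camera adjusted p = 0.00459, adjusted p = 0.484 with an estimated correlation; 0 and 8 with the side as a factor; 2 and 6 with spike-in scaling), with MT-ND1 at −1.95 ± 0.13 and MT-ND4 the 1 that rose, at 0.26 ± 0.08. Histones had 2 and 14 of 26 (camera adjusted p = 0.00168, adjusted p = 0.10 with an estimated correlation; 0 and 10 with the side as a factor). These and the following list examples of total RNA were picked after their values were seen.

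ATF4 targets had 1 higher and 17 lower of 24 (camera adjusted p = 8.9e-07, adjusted p = 0.107 with an estimated correlation; 1 and 16 with the side as a factor; 4 and 15 with spike-in scaling). DDIT4 fell by 2.64 ± 0.11 (edgeR adjusted p = 4.6e-17), SLC7A11, the cystine transporter, fell by 2.12 ± 0.10 and CHAC1 fell by 3.54 ± 0.24, while SLC7A5, an amino acid transporter, rose by 0.82 ± 0.08. Cholesterol biosynthesis genes had 3 and 18 of 24 (camera adjusted p = 1.4e-06, which held at adjusted p = 0.0281 with an estimated correlation; 2 and 17 with the side as a factor; 5 and 14 with spike-in scaling). INSIG1, a brake on cholesterol synthesis (chromosome 7, 155297776 to 155310235) fell from 169 to 37.3 CPM (−2.18 ± 0.08; adjusted p = 9.5e-18). SQLE, an epoxidase of the pathway, was among the 3 that rose (0.58 ± 0.13).

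Haematopoietic transcription factors had 14 higher and 1 lower of 24 (camera adjusted p = 0.00113, adjusted p = 0.255 with an estimated correlation; 12 and 0 with the side as a factor). MYB rose from 130.5 to 301 CPM (1.21 ± 0.07; adjusted p = 4.4e-14), STAT5A by 1.39 ± 0.09 and GATA1 by 0.37 ± 0.08, and ZBTB7A was the 1 that fell (−0.31 ± 0.08, but 0.11 with spike-in scaling). G1/S genes had 17 and 6 of 29 (camera adjusted p = 0.0285, adjusted p = 0.403 with an estimated correlation; 14 and 4 with the side as a factor; 22 and 3 with spike-in scaling), with cyclin E1 (CCNE1) at 1.66 ± 0.13 and cyclin E2 (CCNE2) at −2.64 ± 0.37. Adjusted over the list alone the counts of these 8 lists were the same as over all genes, apart from the ribosomal proteins.

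The remaining 16 lists did not pass at 12 h. Erythroid genes had 9 higher and 21 lower of 38 (camera adjusted p = 0.0631), but 12 and 8 with spike-in scaling, host genes of small nucleolar RNAs 4 and 13 of 24 (0.0789), but 14 and 5, and glycolysis genes 5 and 12 of 19 (0.258), but 8 and 2. Zinc finger genes had 93 and 122 of 395 (0.373), but 131 and 57 with spike-in scaling, and proteasome subunits 11 and 16 of 37 (0.608), but 20 and 4. Interferon response genes had 2 and 9 of 17 (0.104), G2/M genes 17 and 10 of 32 (0.115), immediate early genes 14 and 10 of 34 (0.336), heat shock genes 9 and 8 of 22 (0.545) and p53 targets 7 and 7 of 22 (0.608). With spike-in scaling all of these had more higher than lower members, apart from interferon genes (3 and 5). Interferon genes passed with spike-in scaling (0.0322) and with the side as a factor (0.0482), G2/M genes with spike-in scaling (0.0163), and erythroid and host genes without replicate 2 of 0 h (0.0259 and 0.0335). Genes of mRNA decay had 25 and 20 of 61 (0.755), BCL2 family genes 5 and 4 of 16 (0.768) and elongation and BET genes 13 and 14 of 38 (0.823), but 20 and 4 with spike-in scaling. Of markers of other blood cells, megakaryocyte genes had 0 higher and 2 lower of 3 (0.336), with TUBB1 at −3.83 ± 0.45 and ITGA2B at −1.16. Granulocyte and monocyte genes had 0 and 2 of 8 (0.755) and lymphocyte genes 1 and 0 of 3 (0.778). Adjusted over the list alone, immediate early genes had 14 and 11, heat shock genes 10 and 8 and granulocyte and monocyte genes 0 and 1, and the counts of the other 13 lists were the same.

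**Figure D4:**
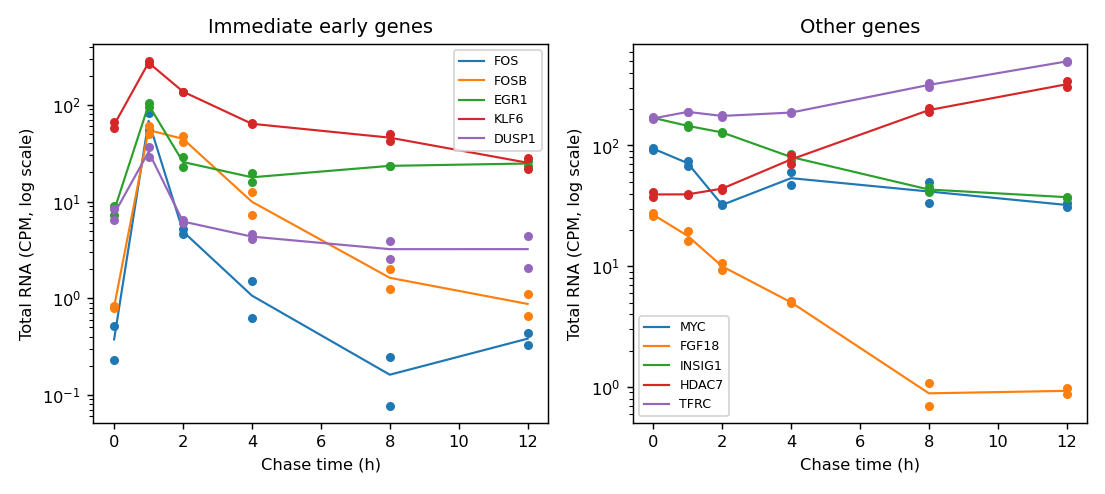
Total RNA in CPM (vertical axes, log scale) against chase time in hours (horizontal axes) for 5 immediate early genes (left) and 5 other genes (right), with 1 point per library and lines through the means of 2 replicates. FOS reached 68.1 CPM at 1 h from 0.375 at 0 h, HDAC7 reached 322 CPM at 12 h from 39.3 (820.5 without 4sU), and FGF18 went from 26.7 to 0.927 CPM.

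The comparison of 0 h with cells that received no 4sU asked what the pulse did to total RNA. Total RNA of HBA2 and SLC3A2 was higher after the pulse, and that of STAT5A and JUNB was lower. HBA2, an alpha globin with a near-identical copy, was at 725.6 ± 44.0 CPM (SD, n = 2) against 111 in the library without 4sU (log2 2.71 ± 0.10; edgeR adjusted p = 1.8e-18). SLC3A2, a subunit of amino acid transporters, was higher by 2.31 ± 0.08 (edgeR adjusted p = 2.0e-18). STAT5A, a signal-activated factor, differed by −2.22 ± 0.10 (edgeR adjusted p = 2.2e-16) and JUNB by −2.32 ± 0.12.

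Of 16255 genes 5448 were higher and 5172 lower at 0 h (4223 and 3928 with the side as a factor), and with spike-in scaling, which moved the median of all genes by 0.48, 7544 were higher and 2987 lower. Of 2267 pseudogenes 1530 were higher and 120 lower, and of 11509 coding genes 3143 and 4640. MT-CO1, a cytochrome oxidase subunit (chromosome M, 5904 to 7445), was at 1.63 ± 0.361 against 146 CPM (−6.48 ± 0.22; adjusted p = 4.9e-19), ADAMTS14, a secreted protease (chromosome 10, 70672803 to 70762441), at 3.08 against 114 CPM, and ARAP3 and S100P, a calcium-binding protein, were lower by −4.62 ± 0.25 and −4.53 ± 0.28. The largest rises had 0 counts without 4sU, so that against a floor of 3 counts H3P47 was at least 427-fold higher, ENSG00000270702 at least 410-fold, RPL15P17 at least 164-fold and RPL15P20 at least 116-fold. The mitochondrially encoded share of all counts went the other way from MT-CO1, at 5.75% ± 0.408 at 0 h against 3.01% without 4sU. Of 12 tested mitochondrially encoded mRNAs 5 were higher and 5 lower, and MT-CYB was at 2444 ± 28.9 against 2449 CPM. Whether reads of MT-CO1 were placed on other genes was not tested, so its fall is uncertain as an effect of the pulse. The side without 4sU has no replicate and was assumed to vary like the other groups.

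Erythroid genes were higher in 24 of 38 and lower in 6 (camera adjusted p = 0.00569, adjusted p = 0.514 with an estimated correlation; 21 and 4 with the side as a factor; 29 and 3 with spike-in scaling), with the blood group protein KEL at 2.36 ± 0.11, and TFRC at −0.91 ± 0.08. ATF4 targets had 17 and 3 of 24 (camera adjusted p = 0.00153, adjusted p = 0.463 with an estimated correlation; 16 and 2 with the side as a factor; 19 and 1 with spike-in scaling), with ASNS, asparagine synthetase, at 392 against 90.5 CPM and CHAC1 at 3.08 ± 0.29. The 3 lower were PCK2 (−1.65), PHGDH (−0.82) and SLC7A5 (−0.28, but 0.20 with spike-in scaling). Zinc finger genes had 170 and 66 of 395 (camera adjusted p = 0.00866, adjusted p = 0.157 with an estimated correlation; 131 and 47 with the side as a factor; 233 and 33 with spike-in scaling), and small nucleolar RNA host genes 15 and 7 of 24 (camera adjusted p = 0.0461, adjusted p = 0.723 with an estimated correlation; 15 and 7 with the side as a factor; 16 and 4 with spike-in scaling). The call of the host genes was lost without replicate 1 of 0 h (0.0641) and without replicate 1 or 2 of 1 h (0.053 and 0.0529).

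Haematopoietic transcription factors had 4 higher and 13 lower of 24, but 8 and 9 with spike-in scaling (camera adjusted p = 0.0446, adjusted p = 0.514 with an estimated correlation; 2 and 13 with the side as a factor). Their call was lost with spike-in scaling (0.148) and without replicate 2 of 0 h (0.0554). SPI1, a myeloid factor, was at −2.51 ± 0.25, GATA2, a progenitor factor, at −1.43 ± 0.12 and GATA1 at −0.93 ± 0.09, while LMO2 (0.86 ± 0.14), STAT5B (0.77), CBFB (0.65) and SOX6 (0.51) were higher. Adjusted over the list alone the counts of these 5 lists were the same as over all genes. The other 19 lists did not pass, among them respiratory chain genes with 39 and 17 of 76 (0.0656), or 59 and 5 with spike-in scaling, interferon response genes with 2 and 10 of 17 (0.0656), G1/S genes with 7 and 15 of 29 (0.0656), but 13 and 8 with spike-in scaling, and ribosomal proteins with 30 and 26 of 84 (0.724), but 65 and 4. Respiratory chain genes passed with spike-in scaling (6.6e-05), with a replicate block (0.0366) and without replicate 2 of 0 h (0.0194), and ribosomal proteins (3.5e-04) and interferon genes (0.0304) with spike-in scaling. ABL1 was at 292 CPM without 4sU, 51.7 ± 6.40 at 0 h and 168 ± 1.24 at 12 h.

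The ratio of total human to spike-in counts was followed as a measure of polyadenylated human RNA per amount of RNA. It was 13 ± 0.029 at 0 h, 13.01 ± 0.306 at 1 h, 13.5 ± 1.15 at 2 h, 13.4 ± 0.075 at 4 h, 14.6 ± 0.858 at 8 h and 15.65 ± 0.977 at 12 h (SD, n = 2), and 9.68 without 4sU. Over the 12 chase libraries its log2 rose with time (Pearson r = 0.866, p = 0.00072; Spearman rho = 0.806, p = 0.00223; permutation tests, two-sided, 100000 resamples). Without the 2 libraries farthest from the median time r was 0.736 (permutation p = 0.0172). Within the 7 libraries of the early spike-in side the relation did not pass (r = 0.311, exact permutation p = 0.459, and rho = 0.33, p = 0.47). These libraries end at 4 h, so they cannot show whether the ratio rose at 8 and 12 h apart from the side. No correlation was computed within the other side, which holds fewer than 6 libraries. The ratios there were 13.4 at 4 h, 13.96 and 15.2 at 8 h and 14.96 and 16.3 at 12 h. The mitochondrially encoded share of counts was 5.75% ± 0.408 at 0 h, 4.39% ± 0.0827 at 12 h and 3.01% without 4sU.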

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

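The tests of labelled RNA in induced genes, of library scaling and of pseudogenes and the test of label as the whole cause were chosen only after the results were seen.

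Of 5839 spike-in genes tested, 214 changed over the chase relative to all spike-in counts (edgeR), a signal in data outside the main measurement. At 12 h against 0 h 198 were lower and 81 higher, and at 0 h against no 4sU 388 were higher and 217 lower. The replicates of 4 h differed across 648 spike-in genes in the way that 8 h differed from 2 h (r = 0.798 across genes, which are not independent replicates). Across total counts of 6846 human genes r was 0.316, and across labelled counts of 3280 human genes it was 0.0674.

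The rate of label loss differed between early and late times in 3210 genes that fell faster later and in 52 that fell slower later, by the test of the quadratic term itself. Scaling is argued against as the cause, since with spike-in sizes or the gene's own total the lower count of genes falling faster later was 2938. For loss of converted reads in T-rich 3' ends at 0 h, a negative partial Spearman rho with T content was predicted, given the labelled share at 0 h. It was 0.135 (0.113 to 0.156) over 8393 coding genes. Such loss would itself lower the labelled share that was held fixed, so this value cannot decide whether it took place. Incorporation of label after the wash remains a candidate explanation, since the 13 genes at least 4-fold higher at 1 h than at 0 h had a median labelled share of 30.4% at 1 h, with 45.0% ± 3.17 in FOS (both libraries together, SD between them). Such late labelling may lengthen half-lives read from the first hours, and regulated decay stays open as untested.

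Annotated pseudogenes at least 8-fold higher at 0 h than without 4sU numbered 884, of which 187 had enough labelled counts and 83 of these carry names of ribosomal protein genes. The median ratio of their labelled share at 12 h to that at 0 h was 0.937 (0.905 to 0.979) against 0.10 in coding genes. For these 187 pseudogenes this argues against their own transcription with a turnover like that of most coding genes. The need for enough labelled counts favours pseudogenes that keep their label. Both this ratio and the labelled share at 12 h may therefore be partly set by the selection. The rest of the 884 pseudogenes were not covered. Transcribed RNA that decays slowly is not excluded, since cytosolic ribosomal protein genes had median labelled shares of 17.2% at 0 h and 13.3% at 12 h. Converted reads of the parent genes placed on pseudogenes remain a candidate explanation, since the median labelled share of these 187 pseudogenes at 12 h was 45.7% (39.9 to 53.9) against 5.56% in coding genes. RPS24P6 was 4.66% ± 0.291 labelled at 0 h, when it was at 1383 CPM. It was 40.7% ± 5.41 labelled at 12 h, when it was at 22.6 CPM (SD, n = 2), and was at 5.82 CPM without 4sU. Its low share at 0 h cannot decide on such placement, since a converted base that matches a C of the pseudogene would not be read as a conversion. No other biological explanation was tested, and the cause in RPS24P6 stays open.

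Total RNA was lower at 0 h than without 4sU in 4640 coding genes. For loss of converted reads in T-rich 3' ends, a negative partial Spearman rho with T content was predicted, given the labelled share at 0 h. It was 0.0895 (0.066 to 0.111) over 8393 genes. Such loss would itself lower the labelled share that was held fixed, so this value cannot decide whether it took place. Of 2950 coding genes that passed at 0 h and were under 5% labelled at 12 h, 1592 (54.0%) passed in the same direction at 12 h against no 4sU, with a median absolute log2 difference of 0.996 at 0 h and 0.485 at 12 h. Label as the whole cause, a lasting response to 4sU and a difference of the lone library without 4sU cannot be told apart by this share, since both comparisons rest on that 1 library, and all 3 stay open.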

How the results depend on the processing

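The window of 2 to 12 h, the omission of pseudogenes and the spike-in side were chosen after seeing the data. Of the answers to comparisons, 406 alternative values were read as the same, 32 weaker, 19 stronger and 19 moved. A count was read as the same within 1.5-fold of the main count. A half-life was read as the same within the SD of the replicate series, and a tested value where its call did not change. Of named slopes 2708 were the same, 57 weaker, 20 stronger and 12 reversed. Of named half-lives 1350 were the same and 587 moved, among them 72 against 27 the same with spike-in sizes, 77 against 20 with the gene's own total, 71 against 24 over 0 to 4 h and 73 against 30 over 2 to 12 h. The cause of the changes was not tested, except that fewer libraries or genes enter shorter windows, omissions and filters. With the gene's own total as the offset, a rising total shortens the half-life and a falling total lengthens it. No half-life was finite in 10 named genes, nor in 20 alternatives of 14 further genes.

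Genes falling faster were 5725 without a filter, 1897 over 0 to 4 h and 2093 with the side (3269 to 3496 without 1 library), and genes falling slower 1673 over 0 to 4 h (3315 to 3529). Genes falling faster later were 366 over 2 to 12 h (2256 to 3356), and slower later 90 with the gene's own total (39 to 68). At 1 h the higher and lower genes were 81 and 26 without a filter and 87 and 17 with the side, and 11 were lower without pseudogenes. Without 0 h replicate 1 they were 29 and 3, without 0 h replicate 2 34 and 3, without 1 h replicate 1 34 and without 1 h replicate 2 32 higher, without 4 h replicate 1 87 and 18, and without 4 h replicate 2 87 and 17. Lower genes with spike-in sizes were 73 at 2 h, 1040 at 4 h, 2008 at 8 h, 2226 at 12 h and 2987 at 0 h against no 4sU. With the side 486 were lower at 2 h, 2514 higher and 2429 lower at 8 h, and 2911 and 3118 at 12 h. At 2 h the counts were 450 and 114 without 0 h replicate 1, 484 and 120 without 0 h replicate 2, 556 and 126 without 2 h replicate 1, and 403 and 89 without 2 h replicate 2; the highest were 1050 higher, and 487 and 488 lower without the replicates of 4 h. Ranges without 1 library were 2123 to 2809 higher and 1459 (0 h replicate 1) to 2526 lower at 4 h, 3308 to 4005 and 3209 to 4251 at 8 h, 3996 to 4583 and 3767 to 4866 at 12 h, 4918 to 5554 and 4737 to 5289 at 0 h against no 4sU, and 9152 to 10479 for any time.

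The median half-life was 5.01 h with spike-in sizes, 3.79 with the gene's own total, 6.26 over 0 to 4 h, 4.72 over 0 to 8 h, 3.755 over 2 to 12 h, 4.46 with 500 labelled counts, 3.65 without a filter, 4.18 without pseudogenes and 4.18 to 4.46 without 1 library. That of the labelled share was 8.64, 6.97 and 6.19 h in these windows and 6.49 to 6.82 without 1 library. The correlation of the spike-in ratio with time was 0.311 within the early side and 0.810 to 0.917 without 1 library. With camera at the preset correlation 11 lists passed for decay (10 to 12 without 1 library), 8 at 12 h (8 to 10) and 5 at 0 h against no 4sU (4 to 5), and with an estimated correlation 2, 1 and 0. At 1 h 1 list passed at the preset correlation and 1 to 5 without 1 library, 3 without 0 h replicate 1, 5 without 0 h replicate 2, 3 without 1 h replicate 1 and 2 without 1 h replicate 2.

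Reversed were the histones by decay with the gene's own total (adjusted p = 0.0475) and ribosomal proteins at 1 h without 0 h replicate 2 (adjusted p = 0.00744, camera in limma, 4.9e-05 to 0.614 without 1 library). Slopes minus the median turned with the gene's own total for TFRC (−0.0906), PSMD7 (0.00785), STAT5A (−0.0440), KIF23 (0.0370), NDUFV3 (0.0493), FOS (0.0375) and PSMD12 (0.0712). Over 0 to 4 h they turned for TFRC (−0.13), ABL1 (0.12), SRF (0.0881), RPL22L1 (−0.14) and SREBF2 (−0.0665). BTF3P7 at 8 h was 0.13 with the side.

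Whether the replicate numbers pair the samples was not settled. Deviations of same-numbered libraries correlated by −0.149 to 0.394 for total RNA (12 of 15 pairs of times positive, 4 over 0.1). For labelled RNA they correlated by −0.0342 to 0.122 (11 of 15 positive, 1 over 0.1). With a replicate block 3437 genes fell faster and 3490 slower, 3169 and 53 departed from 1 rate, and at 1 h 65 were higher and 11 lower. At 12 h 4420 and 4790 passed, and against no 4sU 5402 and 5174.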

Other observations

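The tests of T content and of the AU-rich nonamer were chosen before their results were seen, and the induced genes were picked after.

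Genes that rose in the first hour after the wash carried label. At 1 h the labelled share of the counts of both libraries was 44.3% ± 4.06 (SD between the 2 libraries) in NR4A2, an orphan nuclear receptor, 39.5% ± 3.6 in EGR1, 33.6% ± 1.36 in KLF6, 29.8% ± 0.478 in OSR2, 16% ± 1.6 in FOSB and 12.8% ± 2.72 in MIR23AHG, with 0 labelled counts of these genes without 4sU.

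ABL1 had a half-life of 4.44 h with library scaling and 2.49 h with its own total. Its total RNA was at 292 CPM without 4sU and went from 51.7 ± 6.40 to 168 ± 1.24 CPM between 0 and 12 h.

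AU-rich nonamers (TTATTTATT) in 3' UTRs are bound by proteins that recruit decay factors, and the hypothesis was that coding genes with one have shorter half-lives. The 744 genes with a nonamer had a median of 3.57 h against 4.28 h in 7627 without, a difference within 25 strata of 3' UTR length and T content of −0.12 on the log2 scale (p = 0.0003, 10000 permutations). The 55 genes with at least 3 nonamers had 3.11 h. The nonamer may mark part of the spread of half-lives, and other elements that go with it were not tested.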
